A study of Caenorhabditis elegans with 2 samples.

How the data were processed

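The data are ChIP-seq peak lists of MADF-8 tagged with TY1, eGFP and 3xFLAG, from 2 biological replicates of whole young adult worms (64 hours), immunoprecipitated with an antibody against GFP after sonication. Both replicates form 1 group, taken from the sample labels. For each replicate and for the pair together the authors deposited a ranked list of candidate sites and a list kept at a threshold of the irreproducible discovery rate (IDR), per the file headers and their descriptions on assembly ce11. The lists of the pair were made by the authors from the alignments of both replicates, and those of a replicate from that replicate, each together with a control file that was not analysed here. The aligner, the peak caller and the scaling of the signal are not given in the sources used here. The depth of the libraries is unknown, and intervals cover counting error over sites or genes only.

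The deposited score is the scaled IDR score, whose top value is 1000. The lowest score in each thresholded list was 830, where the −log10 of the global IDR deposited in the ranked list of replicate 1 corresponds to an IDR of 0.00999. The deposited signal is the authors' value per site, used here to describe and rank sites within a list, and across replicates only to describe how matched sites rank. The summit is the deposited offset from the start of the site. The 2 ranked lists of the pair also hold 16 columns of values per replicate that carry no sample name and were not used.

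The main set was the thresholded list of both replicates. Chromosome lengths and names of the reference genome WBcel235 were checked against the sites, and genes were taken from Ensembl release 115, with 19973 protein-coding genes. A gene was bound when a summit lay from 500 bp upstream to 100 bp downstream of the start of 1 of its protein-coding transcripts. Sites were placed at random 1000 times within their chromosomes, keeping widths. Shares of sites on X and in the middle part of autosomes, each divided into 3 of equal length, were tested with exact binomial tests against the shares of protein-coding genes. Median signals were compared by a permutation test with 100000 resamples. The 26 gene lists were fixed before the data were examined, and 5 of their symbols had no match in the annotation. Each list of at least 5 genes and each noncoding class of at least 20 genes was tested with Fisher's exact test and Benjamini-Hochberg adjustment at 0.05. Noncoding classes were set against protein-coding genes by gene start. Genes that share a promoter site are not independent in these tests. Words of 8 bases were counted on both strands within 50 bp of the summit, with 2 control windows for each promoter site.

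Named genes follow a rule fixed before the data were examined. It takes the 15 strongest promoter sites, each by the protein-coding gene with the nearest start, the 3 members with the strongest site in each list past the threshold, madf-8, and the 3 words with the lowest p.

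The alternatives were the conservative set, each replicate alone, the stronger sites by signal, a score of at least 830, wider (1000 bp upstream to 200 bp downstream) and narrower (200 bp upstream to 100 bp downstream) windows, other rules for overlap and for linking sites to genes, other backgrounds, and other control windows, word lengths and window sizes. Alternatives chosen after seeing the data were a score of 1000, merging of overlapping sites, return of the candidates absent from the thresholded list, autosomal genes only, and noncoding genes with no coding start within 1000 bp.

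The list and word tests were tested on simulated data. With 19973 genes, 98% of lists seeded at a raised rate were recovered and 0.246% of unseeded lists were called. The seeded rate was above the share bound in several of the lists tested here. Lists bound less often and sites shared between neighbouring genes were not simulated. For the words, site and control windows were both drawn from random places in the genome. A difference in base composition between bound and unbound promoters was therefore not simulated. Of 5 planted words 5 were recovered and ranked first. Another 45 words were called in those 5 rounds, of which 35 shared 7 bases in a row with the planted word and 44 shared 6, so a count of enriched words includes shifted forms of 1 sequence. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.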

Results

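Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map the sites of MADF-8 in whole young adult Caenorhabditis elegans, 64 hours of age, grown from starved first-stage larvae. MADF-8 carries a MADF domain, a DNA-binding fold related to Myb domains. The worms carried a CRISPR insertion that fuses the protein made from madf-8 to enhanced green fluorescent protein (eGFP), and the chromatin was recovered with an antibody against GFP. The 2 samples are biological replicates of 1 group, so there is no second condition, and the questions addressed are where the sites lie, which genes they mark and how far the replicates share them. The files hold sites and not reads, so the depth of each library is unknown. All coordinates are those of assembly ce11 (WBcel235).

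The set made by the authors from both replicates held 1972 sites, and a companion set named conservative held 1977. The replicate 1 set held 1347 sites and the replicate 2 set 1608. In the set from both replicates, the signal, a value given by the authors for each site, ran from 2.45 to 2985.66, with a median of 119.66. It is 1 value per site and so has no SD. Of the 1972 sites, 1149 overlapped a site in the sets of both replicates, 156 a site of replicate 1 alone, 381 a site of replicate 2 alone and 286 a site of neither. The sites found in both replicates had a median signal of 178.7, and those in neither had a median of 72.9.

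Most sites of replicate 1 were also sites of replicate 2. Of the 1347 sites, 1144 (84.9%, 95% Wilson interval 82.9% to 86.7%) overlapped a site of replicate 2, against a mean of 0.904% and a highest value of 1.86% over 1000 random placements within chromosomes. The one-sided permutation p was 0.001, the smallest that these placements can give. Across the 1144 matched sites the signals of the replicates had a Spearman rho of 0.874. This describes sites, which are not independent replicates.

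**Figure D1:**
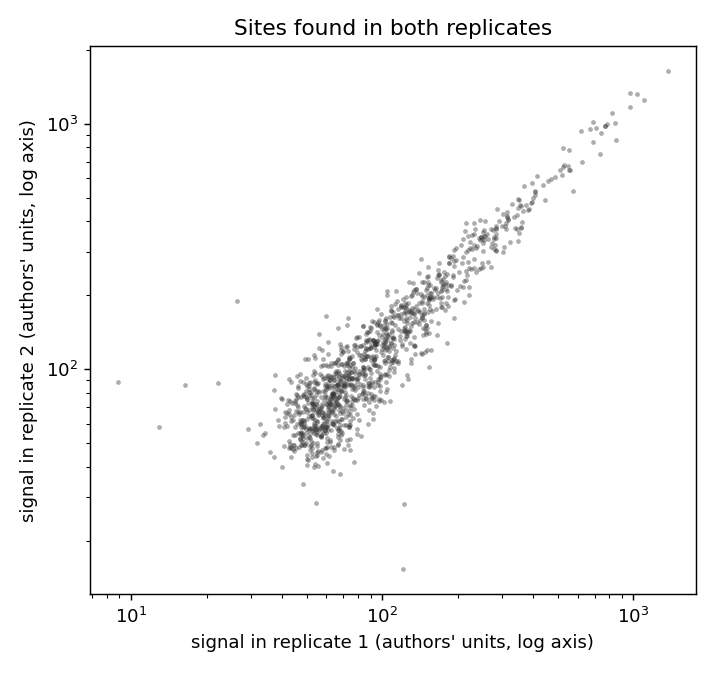
Signal of the 1144 sites found in both replicates, with replicate 1 on the x axis and replicate 2 on the y axis, in the authors' units on log axes. Each point is a site, and the points follow a rising band (Spearman rho 0.874).

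The sites lay mainly just upstream of protein-coding genes. The summits of 1137 sites (57.7%) fell in a promoter window, from 500 bp upstream to 100 bp downstream of a protein-coding transcript start, against a mean of 14.5% over 1000 random placements, a 3.99-fold excess (two-sided permutation p = 0.002, the smallest that these placements can give). Of the promoter sites, 1054 (92.7%) lay upstream of the nearest start. The window itself reaches 500 bp upstream and only 100 bp downstream, so most sites placed in it at random would also lie upstream. This share was not tested. Coding exons held 53 sites, 0.118 times the number placed there at random, and introns held 248, 0.399 times that number (permutation p = 0.002 for each). Intergenic sequence outside promoters held 448 sites, 0.94 times the number at random (permutation p = 0.1). The windows of 1392 of the 19973 protein-coding genes (6.97%) held a site. Promoter sites had a median signal of 131.9 and other sites one of 105.7 (difference 26.1, two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). With a window of 200 bp upstream to 100 bp downstream the promoter share was 32.5% and the signal difference 12.7 (permutation p = 0.00267). Without replicate 1 or without replicate 2 the difference was 15.2 and 9.83, in the units of each replicate's own list (permutation p of 1e-05 and 0.00141).

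The 3 strongest promoter sites, by the nearest gene, were at T19H12.2 (V, 4889986 to 4890332, signal 2351.08), gpi-1 (I, 13575982 to 13576346, signal 2338.9), which encodes glucose-6-phosphate isomerase, and C01G8.1 (I, 5274208 to 5274538, signal 2146.61). They were followed by kin-35, E02C12.12, klp-18, F43G6.16, ppm-2, F26F2.7, hcp-1, nasp-2, rib-2, chs-1, cpg-1 and csc-1, with signals from 1918.54 down to 1215.2. Of these, klp-18 (IV, 7039727 to 7040054) encodes a kinesin of the oocyte meiotic spindle, hcp-1 (V, 6593750 to 6594035) a kinetochore protein and csc-1 (II, 13596601 to 13596894) a subunit of the chromosomal passenger complex. The genes chs-1 (I, 7554617 to 7554923), for chitin synthase, and cpg-1 (III, 4488956 to 4489262), for a chondroitin proteoglycan, act in making the eggshell. All 15 sites were present in the sets of both replicates, and the summit of the site at gpi-1 lay 23 bp downstream of a start while the other summits lay upstream.

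Genes of oogenesis, meiosis, germ granules and cell division had a site at their promoter far more often than other genes, while the sperm list did not (3 of 82, 3.66%). Of 26 gene lists fixed before the data were examined, 10 were bound more often than the other protein-coding genes and 7 less often (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 26 lists). In the cell cycle and DNA replication list 41 of 75 members had a site (54.7%, odds ratio 16.6, adjusted exact p = 6.82e-27), led by klp-18, csc-1 and mcm-2, a subunit of the replicative helicase (II, 12006755 to 12007016, signal 1197.42). Among oogenesis and maternal regulators 30 of 55 were bound (54.5%, odds ratio 16.3, adjusted exact p = 5.36e-20), led by chs-1 and by mex-1 (II, 11968331 to 11968577, signal 928.9) and oma-1 (IV, 8888565 to 8888810, signal 824.0), both CCCH zinc finger proteins of the oocyte and embryo. In the list of meiosis and synapsis 21 of 51 were bound (41.2%, odds ratio 9.47, adjusted exact p = 3.45e-11), with zhp-3, coh-3 and syp-6 the strongest. Of the genes for germ granules and small RNA pathways 21 of 55 were bound (38.2%, odds ratio 8.36, adjusted exact p = 1.61e-10), led by tofu-6 (II, 5421000 to 5421278, signal 1107.56), the nuclear Argonaute gene hrde-1 and the helicase gene glh-2. Among chromatin and synMuv regulators 14 of 46 were bound (30.4%, odds ratio 5.89, adjusted exact p = 5.61e-06), led by lin-9, lin-53 and isw-1. With a window of 200 bp upstream to 100 bp downstream the calls of these lists held with fewer members bound. In the order given, 27, 15, 13, 11 and 8 members were bound, with odds ratios of 15.8, 10.4, 9.42, 6.86 and 5.76.

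Housekeeping lists were bound more often as well. Of the cytosolic ribosomal protein genes 36 of 79 had a site (45.6%, odds ratio 11.4, adjusted exact p = 2.69e-20), with rpl-3, rpl-35 and rpl-20 the strongest, and their summits lay 279, 444 and 288 bp upstream of the start. The proteasome list had 11 of 33 bound (pas-6, rpn-6.1 and rpn-11 leading), oxidative phosphorylation 12 of 39 (cox-5B, cox-5A and cox-16), splicing factors 9 of 30 (rsp-6, snr-4 and rsp-2), and translation factors and tRNA synthetases 13 of 71 (hars-1, eef-2 and eif-2A). Their odds ratios were 6.72, 5.98, 5.75 and 3.01, with adjusted exact p of 2.18e-05, 2.18e-05, 0.000283 and 0.00195. With a window of 200 bp upstream to 100 bp downstream, 4 of the cytosolic ribosomal protein genes were bound and the list was no longer called (adjusted exact p = 0.477), and the calls of the proteasome, splicing and translation lists were also lost (0.0575, 0.13 and 0.0753), with 4, 3 and 6 members bound and odds ratios of 3.75, 3.02 and 2.51. When each site was given to 1 gene only, 22 ribosomal protein genes and 6 oxidative phosphorylation genes were bound and both calls held. The odds ratio of the splicing list was 9.13 without replicate 2 and 3.58 in the stronger sites, with the call held.

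Large families of sensory, metabolic and structural genes were bound less often. Of 1253 chemoreceptor genes 5 were bound (0.399%, odds ratio 0.0501, adjusted exact p = 9.41e-32), namely sri-5, srz-97, srw-90, srh-16 and srh-269. None of the 140 neuropeptide genes had a site (95% Wilson upper limit 2.67%, adjusted exact p = 0.000162). The nuclear hormone receptors had 1 of 269 bound (nhr-47), cytochromes P450 and UGTs 1 of 141 (cyp-31A3), F-box and MATH-BTB genes 8 of 395 (fbxc-23, fbxc-50 and fbxc-44 leading), C-type lectins 5 of 240 (clec-87, clec-88 and clec-91 leading) and cuticle collagens 4 of 180 (col-38, col-2 and col-71 leading). Their adjusted exact p were 6.25e-07, 0.00135, 3.2e-05, 0.002 and 0.0116. The site at fbxc-23 was the same interval as that at csc-1 (II, 13596601 to 13596894). The F-box call was lost with the 200 bp window (adjusted exact p = 0.0575), and the cytochrome call was lost with that window (0.108) and without replicate 2 (0.0514). Without replicate 2 the cytochrome and UGT list had 2 genes bound (odds ratio 0.259, against 0.0947 in the main set). Without replicate 1 or without replicate 2 the bound chemoreceptor genes numbered 3 in each and the bound collagen genes 2 and 3, with both calls held.

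**Figure D2:**
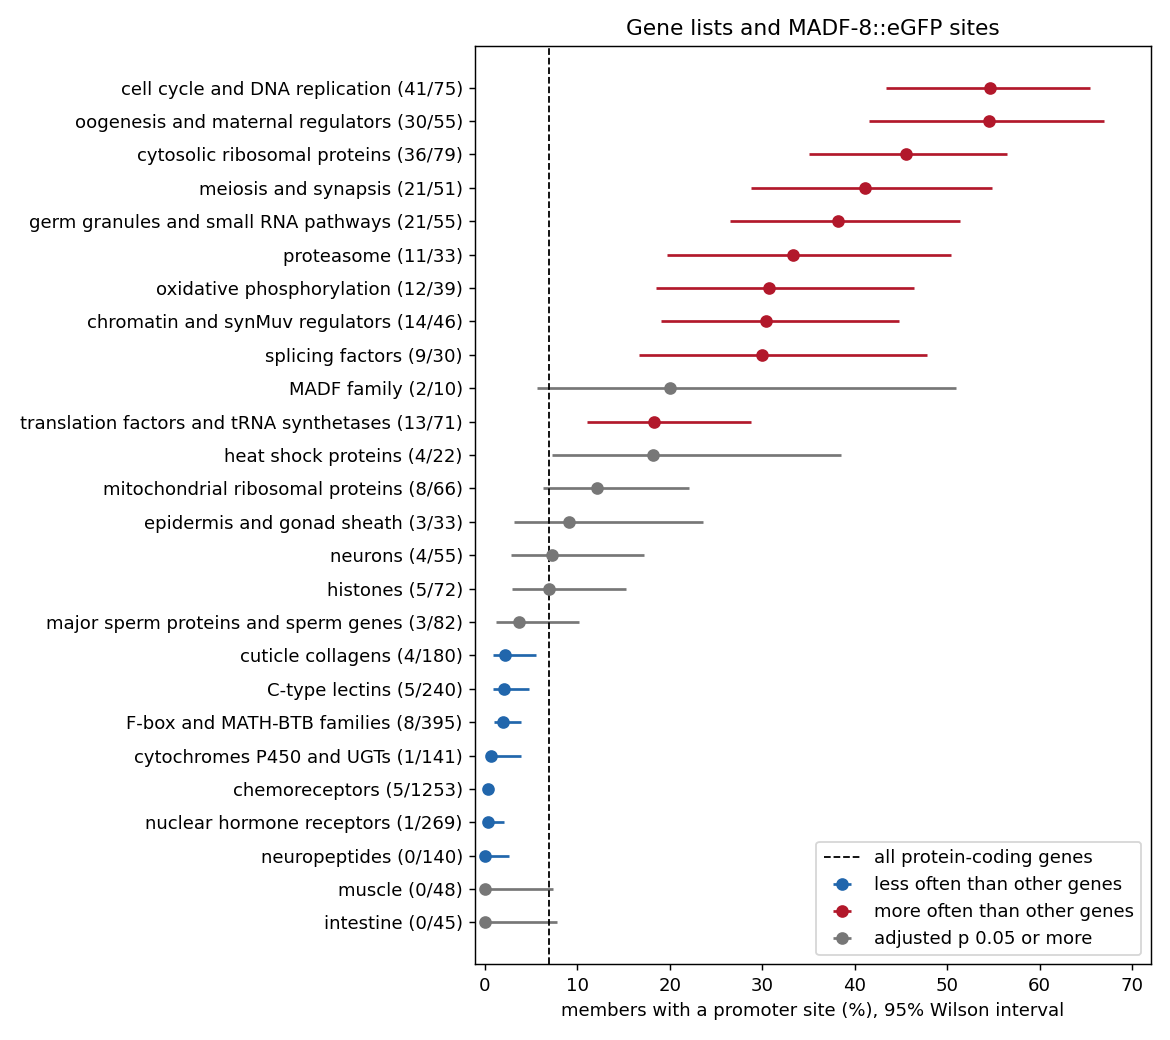
Percent of the members of each of the 26 gene lists with a site summit in the promoter window (x axis), with 95% Wilson intervals and the numbers bound and in the list beside each name. The dashed line marks all protein-coding genes (6.97%). The lists of oogenesis, meiosis, germ granules and cell division lie between 38.2% and 54.7%, as does that of cytosolic ribosomal proteins (45.6%). The sperm list is at 3.66%.

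The remaining 9 lists did not pass the threshold. No member of the intestine list (0 of 45) or the muscle list (0 of 48) was bound, with upper 95% Wilson limits of 7.87% and 7.41% and adjusted exact p of 0.1 and 0.102. Bound members numbered 3 of 82 in the sperm list (spe-39, spe-15 and fog-1), 4 of 55 in the neuron list (unc-11, tdc-1, unc-31 and unc-33), 3 of 33 in the list of epidermis and gonad sheath (inx-14, hmp-1 and inx-22) and 5 of 72 among histones (his-63, his-64, his-67, his-68 and his-74). They numbered 8 of 66 among mitochondrial ribosomal proteins and 4 of 22 among heat shock proteins (hsp-1, hsp-6, hsp-90 and hsp-110). Members named in this paragraph, and the srh chemoreceptors, were chosen after their values were seen. The MADF family had 2 of 10 members bound, madf-6 and madf-8 itself. Without replicate 1 or without replicate 2, 1 MADF gene was bound in each, and 5 and 4 mitochondrial ribosomal protein genes (odds ratios of 1.28 and 1.17, against 1.85). Some of these lists passed the threshold under an alternative. Heat shock proteins were bound more often without replicate 2 (adjusted exact p = 0.0416), in the stronger sites (0.0217), with the window of 1000 bp upstream to 200 bp downstream (0.0138) and by any overlap with the window (0.0329). Their excess was absent when each site was given to 1 gene only (1 of 22, odds ratio 0.815) and with the 200 bp window (0 of 22). Mitochondrial ribosomal proteins were bound more often with the wider window and by any overlap (adjusted exact p of 0.00978 and 0.0447). With that wider window the intestine and muscle lists were bound less often (adjusted exact p of 0.0382 and 0.0259).

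The tagged gene madf-8 (III, 3648792 to 3650832, minus strand) had a site at its own promoter, from 3650700 to 3650975, with a summit 6 bp upstream of the gene start and a signal of 81.2. Of the sites, 79.5% were stronger. The same interval was present in the conservative set and absent from the set of each replicate alone. The ranked lists of the replicates gave overlapping candidates IDR scores of 441 and 178, below the 830 at which the sets begin.

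Few sites lay on the X chromosome. It held 55 of 1972 sites (2.79%), against 13.7% of the protein-coding genes (exact binomial p = 1.54e-62, two-sided). It held 1.8% of the sites without replicate 1 and 0.71% of the stronger sites. Promoters of 21 of the 2731 X-linked genes were bound (0.769%), against 7.95% of autosomal genes, with the highest shares on chromosomes III (11.5%) and I (10.7%) and the lowest autosomal share on V (4.85%). Within autosomes, 732 of 1917 sites (38.2%) lay in the middle part when each chromosome was divided into 3 of equal length, where 38.1% of the autosomal genes start (exact binomial p = 0.944). The 10 lists called as bound more often were also 10 when only autosomal genes were tested, an alternative chosen after seeing the data.

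**Figure D3:**
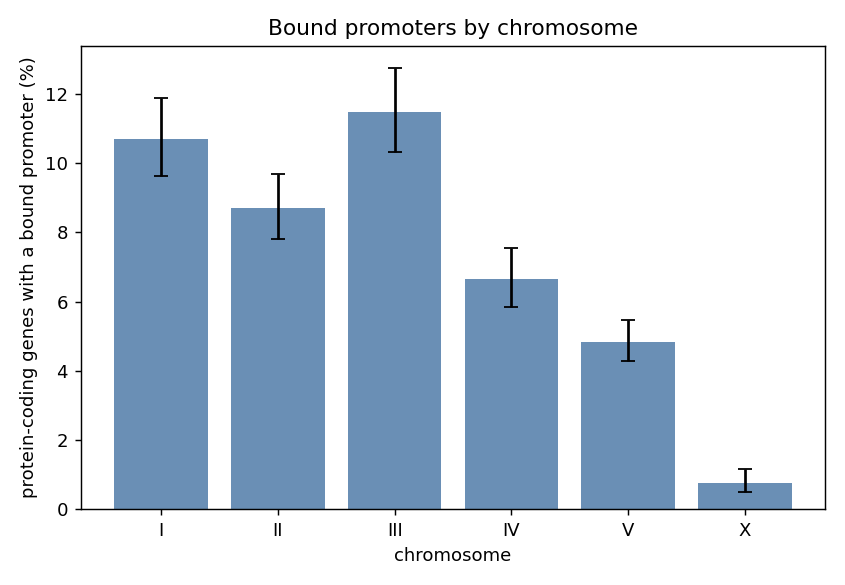
Percent of the protein-coding genes of each chromosome with a site in the promoter window (bars), with 95% Wilson intervals. Chromosome X stands at 0.769%, below the autosomes at 4.85% to 11.5%.

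Among noncoding genes, small nuclear and small nucleolar RNA genes were the most often bound. Of 129 snRNA genes 34 had a site in the same window of their start (26.4%, odds ratio 5.14, adjusted exact p = 4.13e-12), and of 346 snoRNA genes 65 (18.8%, odds ratio 3.32, adjusted exact p = 7.68e-14), against 6.51% of protein-coding genes by gene start. Of 612 tRNA genes 66 were bound (10.8%, odds ratio 1.73, adjusted exact p = 0.000161). With the window of 200 bp upstream to 100 bp downstream 62 tRNA genes were bound (odds ratio 3.32, adjusted exact p = 1.19e-13). The odds ratios of snRNA and snoRNA genes were also higher with that window, at 9.71 and 6.18. Without replicate 2 the bound snoRNA genes numbered 38 (11.0%, odds ratio 2.38), and in the stronger sites 27 snoRNA genes (odds ratio 2.09) and 19 snRNA genes (odds ratio 4.27) were bound, with both calls held. The tRNA call did not hold in either replicate alone (36 and 39 genes bound without replicate 1 and without replicate 2, adjusted exact p of 0.789 and 0.155) and turned round in the stronger sites, where 11 tRNA genes were bound (odds ratio 0.453, adjusted exact p = 0.00864). The piRNA genes had 30 of 15363 bound (0.195%) and the ncRNA class 177 of 7764 (2.28%), against 17 (0.111%) and 113 (1.46%) without replicate 2. These and pseudogenes (48 of 2128) were bound less often than protein-coding genes, and rRNA genes (0 of 20) did not pass the threshold. Antisense RNA (0 of 100), lincRNA (5 of 194) and miRNA genes (9 of 261) were also bound less often in the main set, but these calls were lost in 4, 5 and 8 of 9 alternatives, and all 3 were lost without replicate 2 (adjusted exact p of 0.155, 0.223 and 0.349).

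Some short sequences were more frequent at promoter sites than at unbound promoters. Of 31935 8-mers seen, 761 were more frequent within 50 bp of the summit at the 1137 promoter sites than in 2274 windows at the same distances from the starts of unbound genes (Fisher's exact test, one-sided, adjusted over all 8-mers). The word AAGGCGCA was present at 131 sites (11.5%) and in 0.396% of control windows (adjusted exact p = 8.63e-49). The word GCGAGACC was present at 120 sites (10.6%) and in 0.22% of windows (adjusted exact p = 4.13e-48), and AAAGGCGC, which overlaps the first, at 130 sites (11.4%) and in 0.44% (adjusted exact p = 8.51e-48). Without replicate 1 or without replicate 2, GCGAGACC was in 0.366% and 0.661% of control windows, against 11.2% and 11.7% of sites, and without replicate 2 it ranked 5 by p. Over the alternatives the control shares ran from 0.29% to 0.923% for AAGGCGCA and from 0.361% to 0.88% for AAAGGCGC, and the highest adjusted exact p of the 3 words was 4.07e-32. At least 1 of these 3 words was present at 236 promoter sites (20.8%), so most promoter sites held none of them. Among sites outside promoters AAGGCGCA was present at 12.9%, AAAGGCGC at 13.1% and GCGAGACC at 6.47%. The control windows were matched for distance to a start and not for base composition.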

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

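In the ranked list behind the main set, 92 candidates had an IDR score at or above the lowest score of the set and were absent from it, which is a signal outside the sites analysed in the report. The strongest had a signal of 2076.63 (X, 15810980 to 15811155, intergenic), and only 5 sites of the main set were stronger. Of the 92, 89.1% were intergenic and 17.4% lay on X, against 2.79% of the kept sites (Fisher's exact p = 2.87e-08). Their median share of 31-base words that occur once in the genome was 0.112, against 1 for the kept sites. The thresholded list names 1 further input file, which was not analysed here. Putting the 92 back left the X share at 3.44% and the number of lists bound more often at 10.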

How the results depend on the processing

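The score of at least 830 removed no site, so it tests nothing. Of the 76 other alternative values, 72 kept their direction and their side of the threshold, or stayed within 1.5 times for a count. A score of 1000, merged sites, returned candidates, autosomal genes only and noncoding genes away from coding starts were chosen after seeing the data. A count can stay within that bound while single calls change. The noncoding classes bound more often fell from 3 to 2 in the stronger sites, where the tRNA call turned round (odds ratio 0.453). Enriched words numbered 403 in the upper part of the sites by signal, which holds fewer sites, and 470 for 6-mers, of which fewer exist, against 761. The lists bound more often numbered 6 with the window of 200 bp upstream to 100 bp downstream, against 10. The narrower window was applied to all genes, and the lists differed in where their summits lay. Of the 36 bound cytosolic ribosomal protein genes, 32 had their strongest summit over 200 bp upstream. The same held for 13 of 41 bound cell cycle genes and 8 of 21 bound meiosis genes, lists whose calls held with this window. In the other lists whose calls held, the numbers were 15 of 30 for oogenesis, 10 of 21 for germ granules, 6 of 14 for chromatin and 6 of 12 for oxidative phosphorylation. In the other lists whose calls were lost, they were 7 of 11 for the proteasome, 6 of 9 for splicing and 7 of 13 for translation, so the contrast was smaller there. The share of autosomal sites in the middle part (38.2%) passed the threshold against chromosome length (33.3%, exact binomial p = 8.18e-06) and not against genes, whose own share there is 38.1%. Without replicate 1 or without replicate 2 the promoter share was 59.5% and 61.8%, the X share 1.8% and 2.15%, the lists bound more often 10 and 11, and the noncoding classes 2 in each. The promoter signal difference was 15.2 and 9.83 there, in the units of each replicate's own list. The unknown depth limits what can be said of sites absent from a replicate.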

Other observations

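Some of the strongest sites lay outside the promoter window, although the promoter share was higher in the upper part of the sites by signal (65.1%) than over all sites (57.7%). The strongest of all (I, 13310646 to 13310978, signal 2985.66) lay 844 bp downstream of the nearest coding start, that of T04D3.8, and the next such site (III, 9616963 to 9617280, signal 2294.05) 671 bp upstream of hcp-3, which encodes the centromeric histone H3 variant. Over sites of any strength, 473 (24%) lay over 1000 bp from any coding start, a share that was not set against random placements. The named sites were chosen after their values were seen.

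The tests of this section were chosen after the results were seen, except those on single-copy sequence at the words, on C or G around copies of the words and on the consensus of all genome copies. Sites at promoters of meiosis, oogenesis, germ granule, cell cycle and ribosomal genes could reflect signal at any strongly transcribed promoter of the animal. The intestine and muscle lists, picked after their values were seen, had 0 of 93 genes bound (upper 95% Wilson limit 3.97%, against 6.97% of all protein-coding genes), but over all 4 somatic lists the limit was 7.77%. Of the 3 bound genes that raise it in the epidermis and gonad sheath list, inx-14 and inx-22 are known as germ cell innexins, and without that list, left out after its members were seen, the limit was 6.74%, so the outcome turns on which lists are pooled and this explanation stays open. Germline lists, sperm genes included, had 7.98 times the share of the 4 somatic lists (30.9% against 3.87%), which restates the shares that prompted the question, so germline or growth-related use stays open, as does signal without the tagged protein, since no control was analysed here.

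The words enriched at promoter sites may stem from reads placed wrongly in repeated sequence, but sites with a word had a median single-copy share of 1. The median was also 1 for the other sites, so it does not set them apart. A single-copy share under 0.9 was found at 7.79% of sites with a word and 22.1% of the other sites. Around genome copies of GCGAGACC 4 of 40 flanking positions had a C or G in most copies, between the bounds set for a repeat family and for none, and around AAGGCGCA and AAAGGCGC 0 had, which met the bound for none. That bound misses shared A and T, since positions with any shared base numbered 15 for AAGGCGCA and 12 for AAAGGCGC, against a median of 0 for 10 shuffled words each (highest 0 and 34), and 70.9% of AAAGGCGC copies also hold AAGGCGCA, so a family stays open for both words and for GCGAGACC. Copies closer to the consensus of all genome copies were predicted to lie in sites more often, but lay there less often (lowest ratio 0.402, for AAGGCGCA). The 92 candidates absent from the main set had a median single-copy share of 0.112, so sites in repeated sequence may be missing from it. A lower share in sites could arise that way, so this test does not decide on binding. A sequence learnt from sites on chromosomes I to III gave ratios of 0.84 to 1.4 on the others, all under the 1.5 set for it, the highest for AAAGGCGC (Fisher's exact p = 0.0462, unadjusted), and no biological explanation was tested.

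Sites at small RNA genes could reflect neighbouring protein-coding promoters or reads shared between gene copies. With genes near a coding start left out, the odds ratios stayed at 4.42 for snRNA and 3.07 for snoRNA genes, which argues against neighbours. For tRNA genes the odds ratio fell to 1.12 (adjusted exact p = 0.593), as neighbours would give. With the window of 200 bp upstream to 100 bp downstream it was 3.32 for tRNA genes (adjusted exact p = 1.19e-13). The number of tRNA genes bound did not rise, at 62 against 66. Fewer protein-coding genes were bound in that window, and the odds ratios of snRNA and snoRNA genes rose as well, to 9.71 and 6.18. Genes near a coding start were not left out there, so this rise does not decide on neighbours, which stay open for tRNA genes. The median single-copy share was 0.793 at tRNA sites and 0.81 at snRNA sites, both under 0.9 as shared reads would give, and 1 at snoRNA sites. The prediction took snRNA and snoRNA genes together, so its outcome for the pair was undecided. Shared reads stay open for tRNA and snRNA genes alike. No biological explanation was tested.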
